A study of Homo sapiens with 18 samples.

How the data were processed

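RNA sequencing measured gene expression in 18 libraries of 2 human melanoma cell lines, A375MA2 and SK-MEL-147, written SKMEL147 in group names. Each line carried a non-silencing shRNA (NS, the control), shRNA#1 against G3BP1 (sh1) or shRNA#2 against G3BP1 (sh2), which makes 6 groups of 3 biological replicates as the series design states them. Libraries were made from poly(A) RNA and sequenced on an Illumina HiSeq. The deposited table holds expected counts (estimated reads per gene symbol, not scaled to depth) for 26475 symbols. The authors made them with Bowtie2 2.1.0 and RSEM 1.2.15 on genome build hg38, per the submitters' processing notes. The gene annotation, strand setting and read filters are not given in the sources used here. Every column of the table belonged to 1 library.

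Expected counts were rounded to whole numbers and analysed in R 4.3.3. Within each line the 9 libraries were fitted together with edgeR 4.0.16 (TMM scaling, filterByExpr on the groups, robust quasi-likelihood fit and test). A gene was called at a Benjamini-Hochberg adjusted p below 0.05, and only called genes are said to have risen or fallen. This left 15569 genes tested in A375MA2 and 14997 in SK-MEL-147, of which 14042 were tested in both. Each shRNA was compared with the control of its line, and sh2 with sh1. A gene counted as called with both shRNAs of a line when both tests called it in the same direction. The difference between lines was an interaction test in a fit of all 18 libraries, the mean effect of sh1 and sh2 in A375MA2 minus that in SK-MEL-147, over 16618 genes. All p values are two-sided, all adjusted p values of genes come from edgeR unless DESeq2 or limma is named, and they measure the spread between the 3 biological replicates of each group. Standard errors (SE) of log2 fold changes were taken from the quasi-likelihood F statistic, and mean counts per 1e+06 counts (CPM) are given with the SD over 3 libraries.

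Gene lists covered G3BP1, ESM1, LIMK2 and their paralogs with cofilins (study genes), stress granule proteins, pro-apoptotic genes, anti-apoptotic genes, p53 targets, G2/M genes, G1/S and DNA replication genes, replication-dependent histones, interferon-stimulated genes, MHC class I antigen presentation, NF-kB and inflammatory genes, the integrated stress and unfolded protein responses, heat shock proteins, oxidative stress genes, hypoxia and glycolysis genes, sterol synthesis and uptake, ERK output genes, YAP and TAZ targets, SRF and actin cytoskeleton genes, melanocytic genes, invasive melanoma genes, matrix and adhesion genes, secreted angiogenic factors, lysosome and autophagy genes, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation genes, and markers of fibroblasts, endothelial cells, leukocytes and epithelial cells. Of 31 lists, 30 had at least 5 tested genes and were tested. The remaining list, 13 mitochondrially encoded genes, had fewer than 5 tested genes and was not analysed here. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over all lists and the 4 comparisons of a shRNA with control, and again with an estimated correlation and with fry, which asks whether the genes of a list move one way without comparing them with other genes. Member counts are given over all genes tested and adjusted over the list alone.

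The groups, comparisons, tests, gene lists, other settings and the rule for naming genes were fixed before the data were examined. The rule named 183 genes: the study genes; for each line up to 10 rising and 10 falling genes with the largest smaller change among those called with both shRNAs and with no overlap between the 6 knockdown and 3 control libraries; up to 10 rising and 10 falling genes called in all 4 comparisons; 2 to 4 members of each list; and 5 genes in each direction for the line difference and for sh2 against sh1 in each line, all at a mean of at least 1 CPM. Of these, 4 are not reported here, which leaves 179 named genes, and no others took their place. List members named only to spell out a count of 5 or fewer were chosen after their values were seen. Symbols were matched to GENCODE release 29 for coordinates, transcript length and GC content, with 23925 symbols (90.37%) found, which gave a length for 93.31% of the genes tested in A375MA2 and 93.96% of those in SK-MEL-147.

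The settings fixed in advance as alternatives were DESeq2 size factors or library size in place of TMM, no filter on low counts, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0 (Wald test), limma voom, all 18 libraries in 1 fit, only the 6 libraries compared, replicate number as a block, an absolute log2 fold change of at least 1, leaving out each library, and, for correlations of fold changes, only genes with a mean of at least 10 CPM. A further 3 settings were added after seeing the data. The length and GC trend of each library was removed by offsets from a spline with 5 degrees of freedom, SKMEL147_NS library 2 was used as the only SK-MEL-147 control, and the trend was removed with A375MA2_NS library 3 left out as well. Log-CPM for correlations and principal components used a prior count of 2.

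Total counts ranged from 38.8 to 62.5 M (units of 1e+06) per library. The test was tested on simulated data with known changes at the observed counts and spread. In A375MA2 it recovered 40 of 100 genes changed 1.5-fold and 75 of 100 changed 2-fold with sh1, and 37 and 75 of 100 with sh2. In SK-MEL-147 it recovered 50 of 73 and 51 of 61 with sh1, and 49 of 73 and 51 of 61 with sh2. The line difference was recovered for 6 of 27 genes at 1.5-fold and 26 of 39 at 2-fold. Between 3.03% and 6.92% of calls were false, and no call had the wrong sign. A list shifted on purpose was called in 4 of 4 comparisons, with 0 of 114 calls among other lists. The simulated genes varied independently, with the same spread in all groups of a line and no library-wide length or GC trend. These false shares therefore do not show what correlated genes, such a trend or a wider spread in controls would give. At this spread a gene not called may still differ by 1.5-fold, above all in A375MA2. Because sh1 and sh2 share 3 control libraries, 20 simulations of unchanged groups gave the correlation that sharing produces when each gene varies independently. They hold no library-wide length or GC trend, so they do not show what sharing controls with such a trend would give. Pairs of replicates of a group were checked for duplicated libraries over genes with at least 20 counts, and the smallest chi-square per degree of freedom was 9.491, far above the value of a re-sequenced library. In A375MA2 it was 63.82 to 211 between control libraries, 11.37 to 25.44 with sh1 and 14.69 to 84.48 with sh2. The pooled spread may therefore understate the error of comparisons with that control. Fold changes are relative to TMM scaling, which left the median log2 fold change of all genes between -0.015 and 0.002. Scaling by library size alone moved that median to 0.121 (sh1) and 0.066 (sh2) in A375MA2 and to 0.116 (sh1) and 0.043 (sh2) in SK-MEL-147.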

Results

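Gene expression was measured by RNA sequencing in A375MA2, a metastatic derivative of the A375 melanoma line grown in DMEM, and in SK-MEL-147, a melanoma line grown in RPMI. In each line G3BP1, an RNA-binding protein that nucleates stress granules, was knocked down with 1 of 2 shRNAs (sh1, sh2) and compared with a non-silencing shRNA. There were 3 biological replicates per group and 18 libraries in all. The series names G3BP1 together with ESM1, a secreted proteoglycan, and LIMK2, a kinase of the actin regulator cofilin. The comparisons therefore ask which transcripts differ when G3BP1 is lowered and whether ESM1 is among them. Total counts per library (M, in units of 1e+06) were 41.1 to 50.8 M in A375MA2 controls, 38.8 to 55.5 M with sh1 and 52.2 to 57.7 M with sh2. In SK-MEL-147 they were 45.9 to 62.5 M in controls, 44.8 to 52.9 M with sh1 and 46.4 to 51.7 M with sh2.

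Libraries of a group differed in how gene levels followed transcript length. Spearman's rho across genes between transcript length and a library's deviation from the mean of its line, for which genes are not independent replicates, was -0.22, 0.427 and -0.461 in the 3 A375MA2 controls, -0.063, -0.045 and 0.283 with sh1 and 0.251, 0.42 and -0.232 with sh2. In SK-MEL-147 it was -0.516, 0.037 and -0.487 in the controls and 0.037 to 0.322 in the 6 knockdown libraries. This trend therefore moved with knockdown in that line. Ribosomal RNA genes took 6.16% to 7.27% of counts in SK-MEL-147 controls and 3.93% to 5.85% in its knockdown libraries, against 5.84% to 9.47% and 4.75% to 9.14% in A375MA2. Control library 3 of A375MA2 stood apart on the principal component that held 33.8% of the variance of its line, at 67.24 against -24.2 to 12.52 for the other libraries. Counts of genes are therefore given with all libraries as measured and, as a setting added after these trends were seen, with each library's length and GC trend removed.

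**Figure D1:**
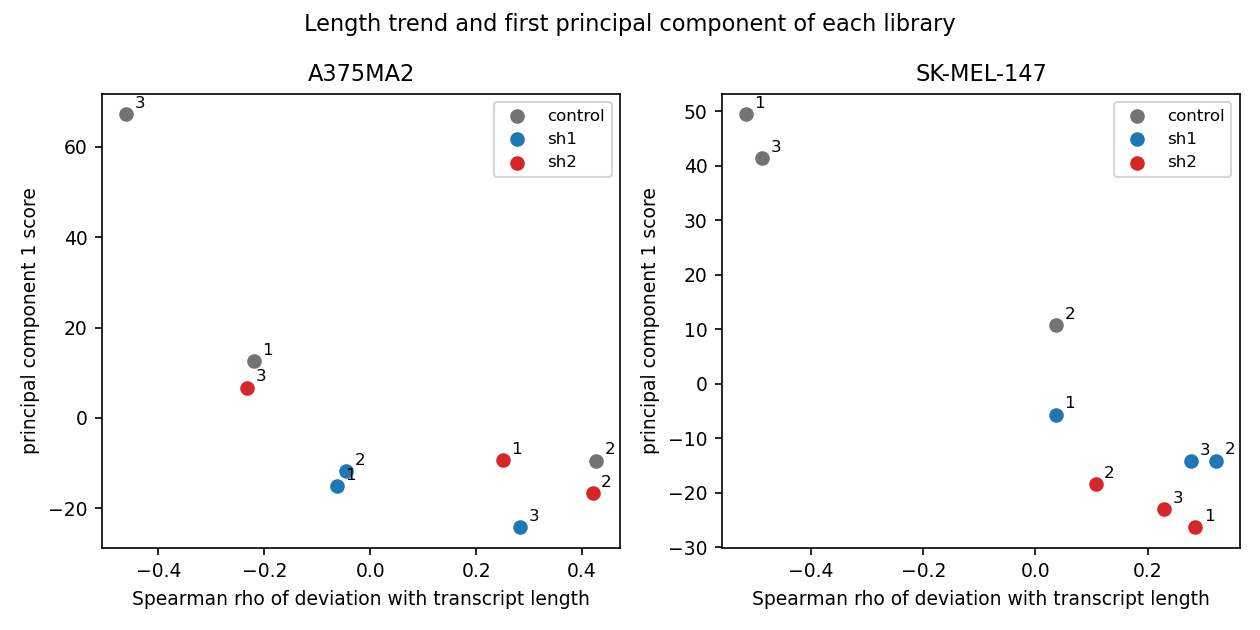
Spearman's rho between transcript length and a library's deviation from the mean of its line (across genes) against the score on principal component 1 (log-CPM), with 1 point per library. A375MA2 control library 3 lies at 67.24 with a rho of -0.461, and SK-MEL-147 control libraries 1 and 3 lie at 49.44 and 41.43 with rho of -0.516 and -0.487.

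G3BP1, the target of both shRNAs, fell in all 4 comparisons with control. In A375MA2 its level was 420 ± 20.4 CPM (SD, n = 3) in controls, 182 ± 3.46 with sh1 and 96.4 ± 3.58 with sh2, or 43.3% and 23% of control in the fit. In SK-MEL-147 it was 181 ± 25.5 CPM in controls, 138 ± 4.65 with sh1 and 89.3 ± 7.54 with sh2, or 76.5% and 49.4% of control. The log2 fold changes were -1.21 ± 0.07 (SE, adjusted p = 5.9e-05) and -2.12 ± 0.07 (1.04e-06) in A375MA2 and -0.39 ± 0.09 (0.00553) and -1.02 ± 0.09 (1.05e-05) in SK-MEL-147. Knockdown was deeper with sh2 than with sh1 in both lines (log2 difference -0.91 ± 0.07 and -0.63 ± 0.09) and deeper in A375MA2 than in SK-MEL-147 (-0.95 ± 0.11 for the mean of both shRNAs). G3BP1 (ENSG00000145907) lies on chromosome 5 from 151771045 to 151812785 on the plus strand of hg38. Each call held in all 20 alternatives run for it. The sh1 value in SK-MEL-147 was -0.7 with the length and GC trend removed and -0.6 with control library 2 as the only control.

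ESM1 fell in all 4 comparisons as well. Its level in A375MA2 was 11.4 ± 1.26 CPM in controls, 5.08 ± 0.272 with sh1 and 2.28 ± 0.191 with sh2, or 44.5% and 19.9% of control. In SK-MEL-147 it was 5.7 ± 0.55 CPM in controls, 2.58 ± 0.379 with sh1 and 1.92 ± 0.137 with sh2, or 45.3% and 33.6% of control. The log2 fold changes were -1.17 ± 0.12 (adjusted p = 0.00065) and -2.32 ± 0.12 (3.7e-05) in A375MA2 and -1.14 ± 0.17 (0.0005) and -1.57 ± 0.18 (6.4e-05) in SK-MEL-147. ESM1 was lower with sh2 than with sh1 in A375MA2 (-1.15 ± 0.12, adjusted p = 0.001), while in SK-MEL-147 this difference was -0.43 ± 0.18 and was not called (adjusted p = 0.1). The mean effect did not differ detectably between lines (-0.38 ± 0.17, adjusted p = 0.17). ESM1 (ENSG00000164283) lies on chromosome 5 from 54977864 to 55022671 on the minus strand of hg38, and its calls held in all 20 alternatives.

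**Figure D2:**
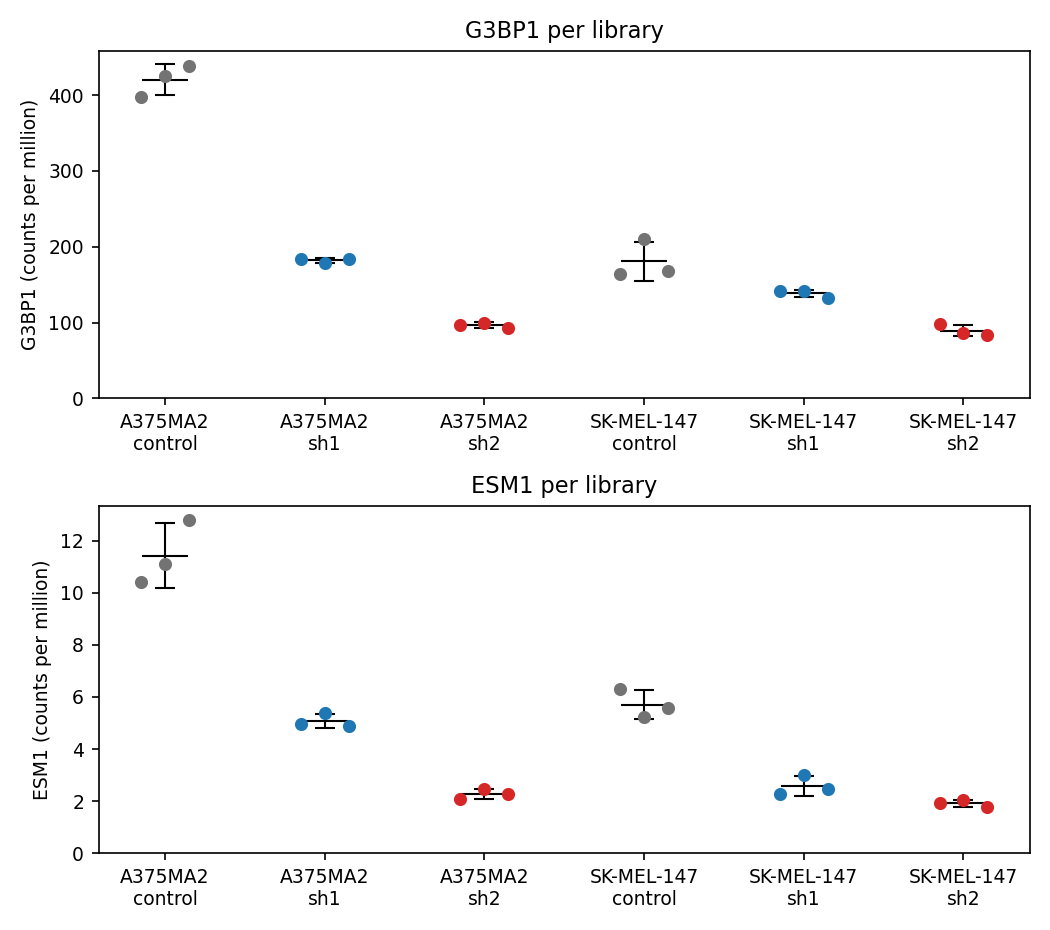
CPM of G3BP1 and ESM1 in each library by line and group, with dots for single libraries and bars for the mean ± SD (n = 3). G3BP1 lies at 398 to 438 CPM in A375MA2 controls and at 92.8 to 100 with sh2, and ESM1 at 10.4 to 12.8 and 2.09 to 2.47.

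LIMK2 was measured at group means of 11.6 to 15.9 CPM and was not called in any comparison, with log2 fold changes from -0.16 ± 0.13 to 0.18 ± 0.09. LIMK1 was not called either. Its level in A375MA2 was 45.1 to 60.7 CPM in controls and 68.2 to 73.9 CPM in the knockdown libraries. In SK-MEL-147 it was 55.1 to 60.6 CPM in controls, 53.9 to 59.5 with sh1 and 63.2 to 65.1 with sh2. G3BP2, the paralog of G3BP1, rose with sh1 in SK-MEL-147 (0.27 ± 0.07). This call was lost without control library 3 (0.2) or sh1 library 2 (0.25) of that line, in a fit of all 18 libraries (0.28) and with control library 2 as the only control (0.11). Cofilin 1 (CFL1), which severs actin filaments, fell in SK-MEL-147 with sh1 (-0.33 ± 0.07) and sh2 (-0.24 ± 0.07). The sh1 value was -0.14 with the trend removed. The sh2 call was lost with 4 of 9 libraries left out in turn and with the trend removed (-0.05, adjusted p = 0.283). CFL2 rose with sh2 in SK-MEL-147 (0.25 ± 0.05), and this call ended too (0.01, adjusted p = 0.922). The study genes are a list of 7 that holds the knockdown target and so is no independent evidence of direction. They were called lower in A375MA2 with sh1 (adjusted p = 0.000858, and 0.0936 with an estimated correlation) and sh2 (1.96e-11, and 0.00955 with an estimated correlation). In both cases only G3BP1 and ESM1 passed the test over all genes. With sh2 the median (0.06) and mean (-0.56) of the list differ in sign. Adjusted over the list alone, 2 members rose and 3 fell with sh1, and 1 rose and 2 fell with sh2. In SK-MEL-147 the list was not called (adjusted p = 0.372 and 0.201), with 1 member rising and 3 falling under each shRNA. It was called lower there with the trend removed (0.043 and 0.00438) and by fry (0.00226 and 0.000625).

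With sh1, A375MA2 cells had less of the chaperones and of the DNA replication genes. HSPA1A, an inducible HSP70, fell from 836 ± 66.7 to 402 ± 29.8 CPM, a log2 fold change of -1.06 ± 0.09 (adjusted p = 0.00041). Its near-identical paralog HSPA1B, with which it can share reads, fell by 1.03 ± 0.07. FEN1, the flap endonuclease of replication, fell by 0.72 ± 0.12 on the log2 scale. PCSK1, a prohormone convertase, rose 3.72-fold (1.90 ± 0.10) and HGF, the ligand of the MET receptor, 2.64-fold (1.40 ± 0.09). SNAI2, a transcription factor of epithelial-mesenchymal transition, rose by 0.98 ± 0.08. DKK1, a secreted WNT antagonist, fell from 32.7 ± 7.94 to 5.04 ± 0.311 CPM (-2.70 ± 0.17).

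Of 16 heat shock genes, 10 fell with sh1 in A375MA2 (12 adjusted over the list alone) and none rose (list adjusted p = 1.02e-13, and 0.00876 with an estimated correlation). Of 30 G1/S genes, 13 fell, 22 adjusted over the list alone, and none rose (7.84e-11, and 0.00881 with an estimated correlation). The other lists called in this comparison lost their call with an estimated correlation, whose adjusted p is given beside each count. The stress response list had 10 of 31 members lower (11 adjusted over the list alone, adjusted p = 6.28e-06, and 0.26 with an estimated correlation), among them CHAC1, which degrades glutathione (-1.19 ± 0.16). YAP and TAZ targets had 6 lower and 2 higher (RBMS3 and F3) of 22, or 8 and 3 adjusted over the list alone (0.00474, and 0.255 with an estimated correlation), with ANKRD1 at -2.67 ± 0.37 and IGFBP3 at -0.67 ± 0.06. In the SRF and actin list 6 of 33 fell, TPM1 by 0.82 ± 0.07, and 1 rose (ACTA2), the same counts as adjusted over the list alone (0.0138, and 0.187 with an estimated correlation). Hypoxia and glycolysis genes had 7 of 29 lower, among them ADM, a vasodilator peptide (-1.21 ± 0.18), and adjusted over the list alone 9 lower and 4 higher (0.031, and 0.26 with an estimated correlation). Oxidative stress genes had 5 of 20 lower (GCLM, HMOX1, SLC7A11, FTH1, NQO1) and 2 higher, AKR1C2 at 1.10 ± 0.10 and AKR1C1, whose call ended with the trend removed (0.47, adjusted p = 0.16), or 7 and 2 adjusted over the list alone (0.013, and 0.349 with an estimated correlation). Replication-dependent histones, whose mRNAs lack a poly(A) tail, were called lower as a list (0.00933, 0.61 with an estimated correlation and 0.0851 with the trend removed) with 1 of 19 called, HIST1H3B, and none adjusted over the list alone. Called higher were sterol genes, with 7 of 24 rising, such as MSMO1 (0.69 ± 0.09) and SC5D (0.54 ± 0.07), and DHCR7 falling, or 9 and 1 adjusted over the list alone (0.00149, and 0.0936 with an estimated correlation). So were leukocyte markers, with CD68 (0.55 ± 0.07) and ITGAM rising of 6, or 3 adjusted over the list alone (0.00683, and 0.14 with an estimated correlation). CD68 is also a lysosomal protein of many cell types.

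In this comparison 1645 of 15569 genes were called, 889 higher and 756 lower. Of these, 262 (201 higher, 61 lower) reached an absolute log2 fold change of at least 1. Removing the trend gave 3787, 1791 higher and 1996 lower. The split by direction depends on scaling, with 1311 higher and 303 lower when scaled by library size alone. The count was 759, 3668 and 2609 without control library 1, 2 or 3, 652, 534 and 507 without sh1 library 1, 2 or 3, and 908 and 1068 without sh2 library 1 or 2. Of the 71 rule-named genes called here besides G3BP1 and ESM1, 48 held their call with each of the 9 libraries left out, among them HSPA1A, HSPA1B, FEN1, PCSK1, HGF, SNAI2, CHAC1, ANKRD1, IGFBP3, TPM1, ADM, GCLM, AKR1C2, MSMO1, SC5D and CD68.

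With sh2, where G3BP1 was lower, fewer A375MA2 genes passed the test. PCSK1 rose 2.42-fold (1.28 ± 0.10, adjusted p = 0.00066), HGF 2.26-fold (1.17 ± 0.09), TGFBI, a matrix adhesion protein, by 0.76 ± 0.09, and SNAI2 by 0.74 ± 0.08. PLK2, a stress-responsive kinase, rose by 0.79 ± 0.07. SHISA2, which retains WNT and FGF receptors in the endoplasmic reticulum, fell from 234 ± 39.1 to 120 ± 7.09 CPM (-0.97 ± 0.11). EHF, an epithelial ETS factor, fell by 1.38 ± 0.16 on the log2 scale. LUM, a collagen-binding proteoglycan, rose by 1.35 ± 0.16.

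The heat shock and G1/S lists were called lower with sh2 as well (adjusted p = 0.00206 and 0.00104, and 0.0936 and 0.0848 with an estimated correlation). Of 16 heat shock genes, 1 (DNAJA1) was called, and 4 adjusted over the list alone. Of 30 G1/S genes, 0 were called by edgeR over all genes or over the list alone, with 13 lower at an unadjusted p below 0.05, 3 lower by DESeq2 and 0 by limma voom. Stress response genes (0.00955, and 0.482 with an estimated correlation) had 0 of 31 called by edgeR, 5 lower adjusted over the list alone, 9 lower and 2 higher at an unadjusted p below 0.05, 5 lower by DESeq2 and 0 by limma voom. Ribosomal protein genes were called lower as a list (0.0116, 0.784 with an estimated correlation and 0.35 with the trend removed) with 0 of 37 members called by edgeR, over the list alone, at an unadjusted p below 0.05, by DESeq2 or by limma voom. Sterol genes had 4 of 24 higher, SC5D (0.64 ± 0.07), DHCR7, MSMO1 and STARD4, or 6 adjusted over the list alone (0.00127, and 0.0936 with an estimated correlation). Melanocytic genes had 3 of 15 higher, the pigment cell regulator MITF (0.36 ± 0.07), GPNMB (0.58 ± 0.07) and DCT (0.91 ± 0.13), or 4 adjusted over the list alone (0.0308, and 0.187 with an estimated correlation). Under sh1, where this list was not called (0.206), MITF (0.45 ± 0.07), GPNMB and EDNRB rose. Matrix and adhesion genes had 4 of 33 higher (SNAI2, TIMP2, CD44, MMP15) and MMP9 lower, or 5 and 2 adjusted over the list alone (0.00933, and 0.453 with an estimated correlation). Fibroblast markers, a cell type foreign to the culture, were called higher (0.00104, and 0.0936 with an estimated correlation) with LUM the 1 of 7 called, and 4 adjusted over the list alone. The list differences between sh2 and sh1 are given with that comparison.

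The sh2 test called 412 genes, 233 higher and 179 lower, with 58 (41 higher, 17 lower) at an absolute log2 fold change of at least 1. It called 1951 with the trend removed, 944 higher and 1007 lower, and by library size alone 210 higher and 108 lower. The count was 88, 2527 and 972 without control library 1, 2 or 3, 174, 143 and 167 without sh1 library 1, 2 or 3, and 34, 54 and 102 without sh2 library 1, 2 or 3. Of 47 rule-named genes called besides G3BP1 and ESM1, 14 held their call with each library left out: CD36, MOXD1, IGFBP5, PCSK1, AZGP1, HGF, EHF, SHISA2, PDLIM7, PLK2, SC5D, TGFBI, SNAI2 and LUM. The calls of MITF, DCT and GPNMB were lost with 7, 3 and 1 of the 9 libraries left out in turn. All 47 held with the trend removed.

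Both shRNAs together called 207 genes in A375MA2, 129 higher and 78 lower, where independent lists of these sizes would share 13.3 and 8.69. Those with the largest smaller change and no overlap between knockdown and control libraries included MOXD1, a monooxygenase-like protein (1.48 ± 0.09 with sh1 and 1.38 ± 0.09 with sh2), and IGFBP5, an IGF-binding protein that rose from 38.2 ± 9.38 to 99.9 ± 6.94 and 98.3 ± 10.6 CPM. They also held the fatty acid receptor CD36 (1.42 ± 0.20 and 1.78 ± 0.19), AZGP1 (1.26 ± 0.14 and 1.24 ± 0.14), PCSK1 and HGF. LRRTM4, CNTN1, NID2 and P2RX7 rose 2.28-fold to 3.28-fold. Falling genes included EHF, SHISA2, the coagulation inhibitor SERPIND1 (-1.38 ± 0.17 and -1.01 ± 0.17), the homeobox gene HHEX (-1.12 ± 0.17 and -0.82 ± 0.17), PLA2G7, TXK, C15orf54 and keratin 18 (KRT18, -0.76 ± 0.11 and -0.77 ± 0.11). The sh2 calls of HHEX, PLA2G7 and TXK were each lost with any of 7 libraries left out. Those of P2RX7 and SERPIND1 were lost with 4, those of CNTN1 and NID2 with 3, those of LRRTM4 and KRT18 with 2 and that of C15orf54 with 1. CD36 (0.461 CPM in controls) and LRRTM4 (0.914 CPM) start from low levels. With the trend removed 1079 genes were called with both shRNAs, 502 higher and 577 lower, against 62.3% higher in the main test and 46.5% with the trend removed. Scaled by library size alone, 133 were higher and 37 lower. Of the 207, 200 were among the 1079 called with the trend removed, in the same direction. The count of 207 was 49, 1470 and 494 without control library 1, 2 or 3, 85, 65 and 72 without sh1 library 1, 2 or 3, and 21, 34 and 56 without sh2 library 1, 2 or 3. Across genes, which are not independent replicates, the log2 fold changes of both shRNAs had a Pearson r of 0.574 and a Spearman rho of 0.544. With the trend removed they were 0.563 and 0.518. The 20 simulations of unchanged groups that share controls gave a mean r of 0.494 and a covariance of 0.037 against 0.11 observed. They called 0 genes with both shRNAs (edgeR, highest of 20 simulations 0). Part of the excess over the simulated values may come from the shared controls, since 3 controls cannot be split into parts of at least 2 libraries.

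In SK-MEL-147, sh1 was accompanied by lower levels of interferon-stimulated genes. BST2, the antiviral tetherin, fell 5-fold from 40.4 ± 3.68 to 8.09 ± 0.629 CPM (log2 fold change -2.32 ± 0.10, adjusted p = 3.7e-08). IFI27 fell by 1.41 ± 0.10 and OASL, an oligoadenylate synthetase-like protein, by 1.26 ± 0.09. The immunoproteasome subunits PSMB9 and PSMB8 fell by 0.70 ± 0.09 and 0.57 ± 0.08. LCN2, an iron-siderophore-binding secreted protein, fell 5.29-fold, and CA9, a carbonic anhydrase induced by hypoxia, from 30.7 ± 4.76 to 9.2 ± 1.88 CPM (-1.74 ± 0.14).

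Of 38 interferon-stimulated genes, 22 fell with sh1 and SAMD9 rose, or 22 and 2 adjusted over the list alone (list adjusted p = 3.71e-15, and 0.0074 with an estimated correlation, the only call of this comparison to hold with it). In antigen presentation 10 of 15 fell, also 10 adjusted over the list alone (4.95e-10, and 0.0737 with an estimated correlation). Hypoxia and glycolysis genes had 17 of 29 lower and 4 higher, or 19 and 4 adjusted over the list alone (6.25e-06, and 0.14 with an estimated correlation), with NDRG1 at -0.68 ± 0.05. Ribosomal protein genes had 34 of 37 lower, or 36 adjusted over the list alone (3.09e-12, and 0.447 with an estimated correlation), RPS14 by 0.50 ± 0.09, but 18 lower and 2 higher with the trend removed. Oxidative phosphorylation genes had 13 of 32 lower and NDUFS1 higher, or 14 and 1 adjusted over the list alone (0.00104, 0.631 with an estimated correlation and 0.134 with the trend removed), with COX5B at -0.48 ± 0.11. These 2 lists hold short transcripts, and SK-MEL-147 control libraries 1 and 3 differ from the knockdown libraries in the length trend. In the p53 list 9 of 29 fell, also 9 adjusted over the list alone (0.00933, and 0.14 with an estimated correlation), among them the stress cytokine GDF15 (-0.75 ± 0.15) and GADD45A (-0.72 ± 0.09). Heat shock genes had 8 of 16 lower, such as HSPB1 (-0.81 ± 0.10), and HSPA4L and HSPA8 higher, the same counts adjusted over the list alone (0.00955, and 0.399 with an estimated correlation). NF-kB genes had 8 of 28 lower, IL32 by 0.60 ± 0.09, and TNFAIP3 higher, also adjusted over the list alone (0.013, 0.26 with an estimated correlation and 0.232 with the trend removed). Melanocytic genes had 7 of 14 lower, or 8 adjusted over the list alone (0.013, and 0.255 with an estimated correlation), with the endothelin receptor EDNRB at -1.13 ± 0.15. Of 6 epithelial markers KRT7, KRT8 (-0.77 ± 0.10) and KRT18 fell, also adjusted over the list alone (0.0165, and 0.26 with an estimated correlation). Called higher were G1/S genes, with 12 of 30 rising, such as cyclin E2 (CCNE2, 0.63 ± 0.11), and CDT1 and MCM7 falling, also adjusted over the list alone (0.00474, and 0.26 with an estimated correlation). So were YAP and TAZ targets, with 9 of 22 rising, such as ANKRD1 (0.46 ± 0.09), and IGFBP3, GADD45B and CYR61 falling, or 12 and 3 adjusted over the list alone (0.0241, and 0.447 with an estimated correlation).

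In this comparison 4823 of 14997 genes were called, 2266 higher and 2557 lower. Of these, 227 (113 higher, 114 lower) reached an absolute log2 fold change of at least 1. Removing the trend gave 4513, 2018 higher and 2495 lower. Scaling by library size alone turned the near balance into 3776 higher and 1384 lower. The count was 3041 and 2669 without control library 1 or 3 and 2767 and 2885 without sh1 library 2 or 3. Control library 2 as the only control gave 1357. Of 100 rule-named genes called, 66 held with each library left out. The calls of 22 were lost with the trend removed, among them NDUFB8 (-0.07), PSMB10 (-0.13), BAX (0.01) and PFN1 (-0.06), while RPS3 (-0.33 to -0.26), RPS19 (-0.39 to -0.28) and IL6 (-0.54 to -0.38) kept most of their change. The calls of PSMB9 (-0.37), PSMB8 (-0.31), COX5B (-0.17), GDF15 (-0.44), HSPB1 (-0.46) and IL32 (-0.32) held without the trend at smaller values.

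With sh2 in SK-MEL-147, hypoxia and glycolysis genes were lower as a group. CA9 fell from 30.7 ± 4.76 to 7.01 ± 0.268 CPM (-2.13 ± 0.14, adjusted p = 1e-06), NDRG1 from 1250 ± 4.94 to 655 ± 16.2 CPM (-0.93 ± 0.05) and ANKRD37 by 1.01 ± 0.22 on the log2 scale. LCN2 fell 14.8-fold to 2.19 ± 0.452 CPM, BST2 4.39-fold and the cytokine IL6 by 1.19 ± 0.16. TIE1, an endothelial receptor kinase measured at 64.3 CPM in these controls, fell by 1.44 ± 0.09. CACNA1E, a calcium channel subunit, rose from 0.27 ± 0.0212 to 3.74 ± 0.464 CPM (3.78 ± 0.31).

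Of 29 hypoxia and glycolysis genes, 24 fell with sh2 and KDM3A rose, or 24 and 2 adjusted over the list alone (list adjusted p = 4.54e-15, and 0.0401 with an estimated correlation, the only call of this comparison to hold with it). Stress response genes had 19 of 31 lower, such as the transcription factors DDIT3 (-0.59 ± 0.08) and ATF3 (-0.56 ± 0.06), and EDEM1 and ATF6 higher, or 20 and 3 adjusted over the list alone (9.39e-06, and 0.26 with an estimated correlation). G1/S genes had 13 of 30 lower, among them the origin licensing factor CDT1 (-0.40 ± 0.09), or 14 adjusted over the list alone (0.000192, and 0.187 with an estimated correlation). Ribosomal protein genes had 20 of 37 lower, or 23 adjusted over the list alone (9.52e-06, 0.631 with an estimated correlation and 0.274 with the trend removed), with RPS14 at -0.50 ± 0.09. NF-kB genes had 12 of 28 lower, CSF2 by 0.53 ± 0.11, and IL24, LIF and IL1A higher, or 13 and 3 adjusted over the list alone (0.00402, and 0.211 with an estimated correlation). In the p53 list 11 of 29 fell, GDF15 by 1.16 ± 0.15, and TP53INP1, ZMAT3, POLH and MDM2 rose, or 12 and 4 adjusted over the list alone (0.013, and 0.172 with an estimated correlation). Invasive melanoma genes had 13 of 28 lower, such as INHBA (-0.79 ± 0.07), and 6 higher, such as EGFR (0.52 ± 0.11), or 13 and 7 adjusted over the list alone (0.0232, and 0.218 with an estimated correlation). Of 5 endothelial markers TIE1 alone fell, also adjusted over the list alone (0.013, and 0.172 with an estimated correlation). Of 6 epithelial markers KRT7 (-1.36 ± 0.21), KRT8 and KRT18 fell, also adjusted over the list alone (0.013, and 0.26 with an estimated correlation), the KRT18 call ending with the trend removed (-0.12, adjusted p = 0.0745). Called higher were sterol genes, with 9 of 25 rising, MSMO1 by 0.44 ± 0.06, and PMVK and FDPS falling, or 13 and 3 adjusted over the list alone (0.00955, and 0.135 with an estimated correlation). So were ERK output genes, with 11 of 20 rising and IER3, ETV4 and FOSL1 falling, or 11 and 6 adjusted over the list alone (0.013, and 0.14 with an estimated correlation). Stress granule proteins other than G3BP1 had 12 of 24 higher, NUFIP2 by 0.68 ± 0.16, and FXR2 and YBX1 lower, or 13 and 2 adjusted over the list alone (0.00955, 0.561 with an estimated correlation and 0.305 with the trend removed). Interferon-stimulated genes were not called as a list (adjusted p = 0.595), with 11 of 38 rising and 6 falling, or 14 and 7 adjusted over the list alone.

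The sh2 test called 4740 genes, 2417 higher and 2323 lower, with 359 (141 higher, 218 lower) at an absolute log2 fold change of at least 1. It called 4616 with the trend removed, 2354 higher and 2262 lower, and by library size alone 3045 higher and 1703 lower. The count was 3137 and 2778 without control library 1 or 3 and 3022 and 3093 without sh2 library 1 or 3. Control library 2 as the only control gave 1422. Of 103 rule-named genes called, 75 held with each library left out. The calls of 16 were lost with the trend removed, among them CFL1, CFL2, KRT18, ZYX, HSPB1 (-0.41 to -0.11), BBC3 (-0.43 to -0.14), CHAC1 (-0.47 to -0.22) and EPHA4 (0.44 to 0.22). Those of EGFR (0.20), NUFIP2 (0.36), CDT1 (-0.23), CSF2 (-0.29) and DDIT3 (-0.36) held without the trend at smaller values.

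**Figure D3:**
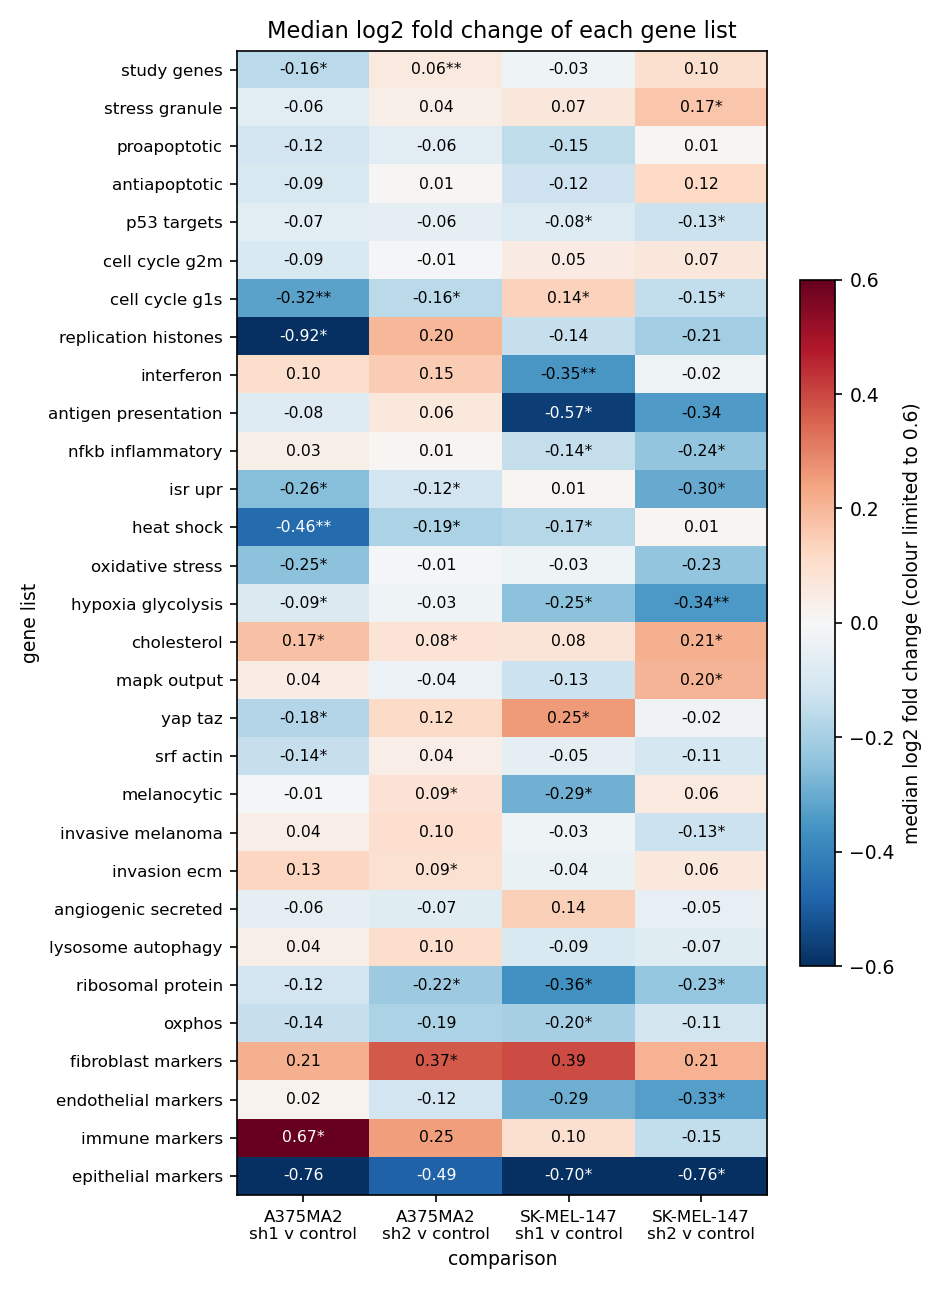
Median log2 fold change of each gene list in the 4 comparisons with control, with 1 asterisk where camera called the list and 2 where it also did so with an estimated correlation. Interferon-stimulated genes lie at -0.35 with sh1 in SK-MEL-147 and hypoxia and glycolysis genes at -0.34 with sh2.

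Both shRNAs together called 2295 genes in SK-MEL-147, 1118 higher and 1177 lower, where independent lists of these sizes would share 365 and 396. Among the falling genes with the largest smaller change were LCN2, BST2, CA9 and the dioxin-inducible CYP1A1 (-1.73 ± 0.20 with sh1 and -1.54 ± 0.20 with sh2). Others were the potassium-chloride cotransporter SLC12A7 (-1.82 ± 0.21 and -1.49 ± 0.20), the epithelial factor ELF3 (-1.55 ± 0.27 and -2.03 ± 0.27), MPPED2, SCARF2 and the loci LOC642423 and UQCRBP1. UQCRBP1 is a pseudogene that can take reads of UQCRB. Its call was lost with 1 library left out for sh1 and with 5 for sh2. Rising genes included PRKAR2A, a regulatory subunit of protein kinase A (7.31 ± 2.56 to 16.4 ± 2.27 and 17.3 ± 1.24 CPM), ZNF704 (1.08 ± 0.14 and 1.22 ± 0.14), CACNA1E, ASXL2, GPRIN3, SPTBN5, LOC441155, LMBRD2, LNPEP and NPTN-IT1, the last of which lies within NPTN. LNPEP was lost with 8 libraries left out for sh1 and 4 for sh2, LMBRD2 with 3 and 6, and NPTN-IT1 with 3 and 3. The sh1 call of SPTBN5 and the sh2 calls of GPRIN3 and LOC441155 were lost with 3, and the sh2 call of ASXL2 with 1. Without the trend 1806 genes were called with both shRNAs, 804 higher and 1002 lower, and 1216 of the 2295 kept the call in the same direction. By library size alone 1904 were higher and 633 lower. The count of 2295 was 1168, 4432 and 1023 without control library 1, 2 or 3, 1354 and 1377 without sh1 library 2 or 3, and 1489 and 1471 without sh2 library 1 or 3. It was 332 with control library 2 as the only control. Across genes, which are not independent replicates, the fold changes of both shRNAs had a Pearson r of 0.544 and a Spearman rho of 0.564. With the trend removed they were 0.498 and 0.444. The 20 simulations of unchanged groups that share controls gave a mean r of 0.515, with a covariance of 0.0505 against 0.144 observed and at most 1 gene called with both. These simulations hold no library-wide trend, and the r with the trend removed lies below their mean.

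Set against sh1, sh2 in A375MA2 went with more heat shock and G1/S expression. DKK1 was higher with sh2 (21.8 ± 1.14 against 5.04 ± 0.311 CPM, log2 difference 2.12 ± 0.16), as were the tight junction gene CLDN1 (1.86 ± 0.21), SLC18A1 (1.55 ± 0.15) and LINC00707 (1.70 ± 0.25). EDN3, the ligand of EDNRB, was higher with sh1 (-2.45 ± 0.16), as were SAMD11, UBD, MAOB and MYCN. In the lists, sh2 was higher for heat shock genes (adjusted p = 1.66e-07, and 0.0148 with an estimated correlation) and G1/S genes (6.69e-05, and 0.0234). It was also higher for YAP and TAZ targets (1.66e-07), oxidative stress genes (2.03e-05) and histones (6.87e-05), whose p with an estimated correlation were 0.0572, 0.115 and 0.419. Stress response (0.013), SRF (0.0188) and hypoxia genes (0.0251) were higher too, and leukocyte markers (0.0197) and study genes (0.0286) lower, with p of 0.477, 0.145, 0.215, 0.136 and 0.154. The test called 883 genes, 378 higher with sh2 and 505 lower, and 2451 with the trend removed, 1202 higher and 1249 lower, and by library size alone 190 higher and 553 lower. The count was 1354 and 2469 without control library 2 or 3, 275, 258 and 304 without sh1 library 1, 2 or 3, and 253, 253 and 324 without sh2 library 1, 2 or 3.

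In SK-MEL-147, interferon-stimulated genes were higher with sh2 than with sh1 (median log2 difference 0.40, list adjusted p = 1.38e-15, and 0.00525 with an estimated correlation), G1/S genes lower (-0.31, 1.51e-15, and 0.0201) and ERK output genes higher (0.25, 2.05e-06, and 0.0175). Antigen presentation (2.03e-05) and melanocytic genes (0.000584) were higher with sh2, and stress response (0.000244) and hypoxia genes (0.000972) lower, with p of 0.105, 0.112, 0.339 and 0.189 with an estimated correlation. Also higher were anti-apoptotic (0.00957, and 0.105 with an estimated correlation), heat shock (0.013, and 0.402), matrix (0.0153, and 0.183), ribosomal protein (0.0209, and 0.758) and sterol genes (0.0295, and 0.136). Invasive melanoma genes (0.00166, and 0.105) and YAP and TAZ targets (0.00639, and 0.345) were lower. Among single genes CACNA1E (2.42 ± 0.28), the ferritin receptor SCARA5 (2.09 ± 0.22), the proton pump subunit ATP6V0A4 (1.84 ± 0.26) and LOC101929427 were higher with sh2. By contrast, ENPP5 (-2.13 ± 0.29), ZNF594 (-1.86 ± 0.29), PAQR8 and ALS2CL were higher with sh1. The read-through transcript DYX1C1-CCPG1 (3.92 ± 0.77) and DYX1C1 (-2.13 ± 0.52) overlap each other, so their reads cannot be assigned to 1 of them with certainty. The test called 3247 genes, 1772 higher with sh2 and 1475 lower, and 4762 with the trend removed, 2604 higher and 2158 lower. By library size alone the majority turned, with 1184 higher and 2069 lower. The count was 2050 and 2110 without sh1 library 2 or 3 and 2029 without sh2 library 3.

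In all 4 comparisons 21 of 14042 genes were called in the same direction, 10 higher and 11 lower. Besides G3BP1 and ESM1, those lower included the actin-associated PDLIM7 (-0.58 ± 0.08, -0.67 ± 0.08, -0.35 ± 0.07 and -0.48 ± 0.07 for sh1 and sh2 in A375MA2 and in SK-MEL-147) and the focal adhesion protein zyxin (ZYX). Also lower were the LIM protein FHL2, KRT18, DEPDC7, DNTTIP1, SHISA2, TTC1 and the proteasome ubiquitin receptor ADRM1. Higher were ZNF704, KIAA1467 (0.44 ± 0.08, 0.47 ± 0.08, 0.61 ± 0.09 and 0.49 ± 0.09), MOXD1, the heparan sulfate proteoglycan GPC6, the semaphorin SEMA3C, the anthrax toxin receptor ANTXR2, the metalloprotease inhibitor TIMP2, the sterol enzyme MSMO1, RHOQ and SETBP1. Chance overlap of both lines' lists would give 8.31 higher and 6.33 lower (Fisher's exact p = 0.471 and 0.0601), so the overlap of the lines did not exceed chance in this test. Removing the trend gave 124 such genes, 40 higher and 84 lower, against 24.7 and 39.5 by chance (Fisher's exact p = 0.00298 and 3.31e-11). Fisher's test takes genes as independent, which they are not. Of the 21 genes, 11 were among the 124. The share called higher went from 47.6% to 32.3%. By library size alone 15 were higher and 7 lower. Besides G3BP1, ESM1 and PDLIM7, each of these genes run with libraries left out lost at least 1 of its calls, FHL2, SEMA3C and ADRM1 with 8 of 9 libraries. In SK-MEL-147 the trend-removed values of ANTXR2 (-0.04) and ADRM1 (0.04) with sh1 and of ZYX (0.03) with sh2 had the opposite sign and were not called. The calls of GPC6, SEMA3C, DNTTIP1 and PDLIM7 (-0.07) with sh1 and of KRT18 and ADRM1 with sh2 ended. PDLIM7 with sh2 held at -0.21. The count of 21 was 9, 358 and 54 without A375MA2 control library 1, 2 or 3, between 5 and 9 without any 1 of its knockdown libraries. It was 10, 41 and 8 without SK-MEL-147 control library 1, 2 or 3, and 10 without sh1 library 2 or 3 of that line. Across genes, which are not independent replicates, the mean effects in both lines had a Pearson r of 0.18 and a Spearman rho of 0.295. With the trend removed they were 0.117 and 0.184. Pearson's r was 0.427 among genes with a mean of at least 10 CPM, for which no value without the trend was obtained. It was -0.002 without A375MA2 control library 3.

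**Figure D4:**
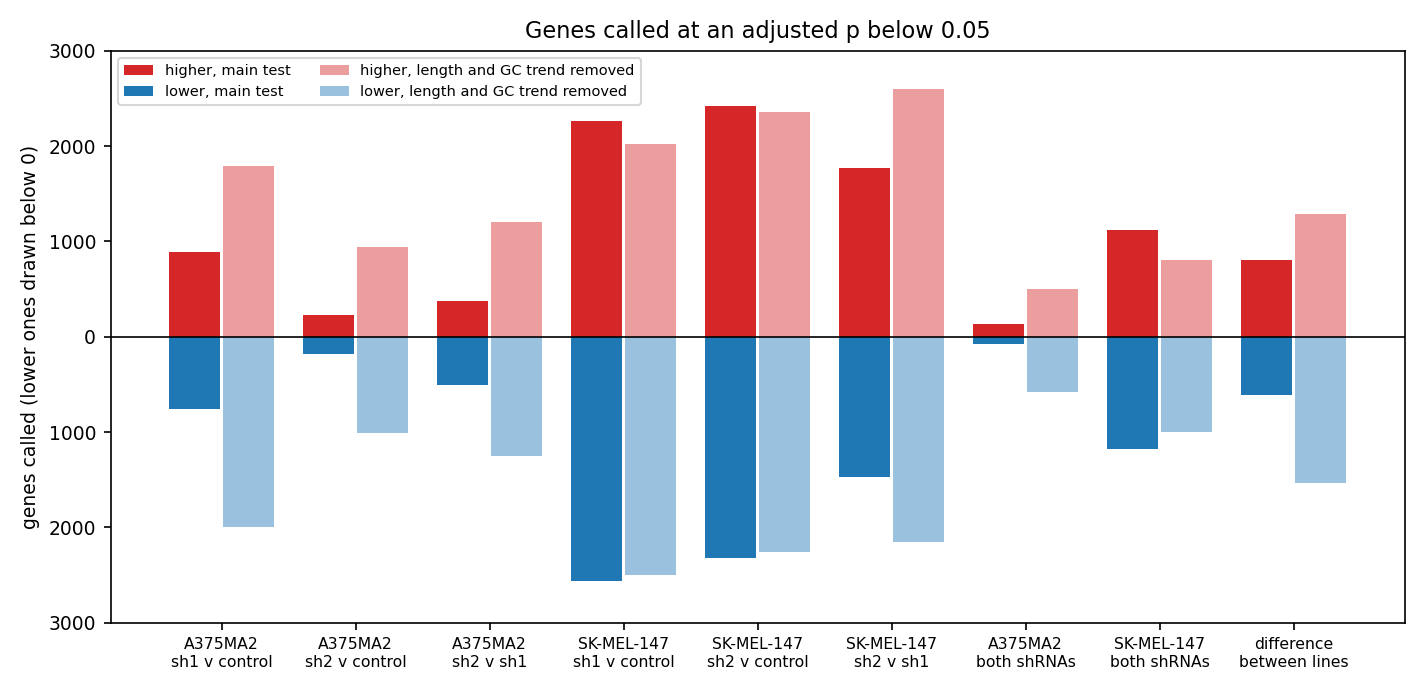
Numbers of genes called higher (above 0) and lower (below 0) in each comparison, in the main test and with the length and GC trend of each library removed. A375MA2 with sh2 has 412 called genes and 1951 with the trend removed, and SK-MEL-147 with sh1 has 4823 and 4513.

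The knockdown effect differed between the lines for 1421 of 16618 genes, 805 with the higher effect in A375MA2 and 616 in SK-MEL-147. The effect is the signed log2 fold change, so a gene that fell further in SK-MEL-147 has the higher effect in A375MA2. IGFBP5 rose with both shRNAs in A375MA2 and fell in SK-MEL-147 (-1.25 ± 0.14 and -0.74 ± 0.14), a difference of 2.38 ± 0.20 on the log2 scale. BST2 fell in SK-MEL-147 and rose with sh1 in A375MA2 (0.79 ± 0.17, a call lost without sh1 library 1, 2 or 3, at 0.75, 0.79 and 0.84), a difference of 2.94 ± 0.16. LCN2 (2.41 ± 0.20), MPPED2 (2.51 ± 0.29) and UBD, a ubiquitin-like protein induced by interferon (3.43 ± 0.34), also had the higher effect in A375MA2. ANKRD1, a YAP target, fell with sh1 in A375MA2 and rose in SK-MEL-147 (-2.73 ± 0.25). FAM160A1 (-1.77 ± 0.42), SPTBN5 (-1.87 ± 0.47) and the loci ZNF321P and RPLP0P2, a pseudogene that can take reads of RPLP0, had the higher effect in SK-MEL-147. Among lists, p53 targets (adjusted p = 0.00198, and 0.0201 with an estimated correlation), interferon-stimulated genes (5.02e-05, and 0.0148) and hypoxia genes (2.03e-05, and 0.0148) had the higher signed effect in A375MA2. Hypoxia genes fell further in SK-MEL-147 (medians -0.247 and -0.343 with sh1 and sh2) than in A375MA2 (-0.089 and -0.027). The lower signed effect in A375MA2 was seen for G1/S (2.03e-05, and 0.00725) and heat shock genes (5.17e-05, and 0.0402). Heat shock medians were -0.461 and -0.189 in A375MA2 and -0.172 and 0.014 in SK-MEL-147. Without the trend 2822 genes differed, 1286 and 1536, the share higher in A375MA2 going from 56.7% to 45.6%. By library size alone 716 and 450 differed. The count was 2926 without A375MA2 control library 3, 818 and 770 without SK-MEL-147 control library 1 or 3, and 238 with SK-MEL-147 control library 2 as the only control.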

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

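Of the tests in this part, 3 were chosen only after the result was seen: the number of SK-MEL-147 genes that keep their call without the length and GC trend, the G3BP1 level of A375MA2 control library 3 and the share of RNA of the other line in that library. The removal of the trend was itself added after seeing the data. Groups of 3 libraries are too small to be tested for a single deviating library.

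The knockdown effect differed between the lines, by the interaction test in all 18 libraries, for 62 of the 179 named genes. It was higher in A375MA2 for 39 and in SK-MEL-147 for 23. Over all 16618 genes tested, 1421 (8.55%) differed. Some named genes were picked for this difference and others for large changes within a line, so the larger share among them is no separate result. Values are the signed log2 effect in A375MA2 minus that in SK-MEL-147, so a value above 0 can mean a deeper fall in SK-MEL-147. Among interferon and inflammation genes they were 3.43 for UBD, 2.94 for BST2, 2.24 for OASL, 1.75 for IFI27 and 2.41 for LCN2. Secreted, matrix and surface proteins had 5.09 for FAP, 2.38 for IGFBP5, 1.55 for CNTN1, 1.15 for MOXD1, 1.07 for NID2, 0.95 for AZGP1, 0.9 for TGFBI, 0.84 for COL6A2, 0.74 for LUM and 0.44 for ANTXR2. Others had 1.19 for EDNRB, 1.48 for TIE1, 1.23 for ESAM, 1.49 for SCARF2, 1.57 for SLC12A7, -0.73 for ANGPTL4, -1.33 for DKK1, -1.53 for LNPEP and -2.8 for SERPIND1. Genes of stress, death and metabolism had 3.55 for CA9, 2.16 for AKR1C2, 1.77 for CYP1A1, 1.29 for GDF15, 0.83 for BMF, 0.83 for GABARAPL1, 0.66 for PLK2, 0.64 for BBC3, 0.63 for ATF3, 0.59 for NDRG1, 0.41 for WIPI1, 0.35 for DHCR7 and 0.29 for MSMO1. Below 0 were -0.33 for BAG3, -0.44 for HSPA1A, -0.43 for HSPA1B, -0.51 for PRRC2C, -0.89 for GCLM and -0.95 for G3BP1. Regulators, cytoskeletal and cell cycle genes had 3.4 for ELF3, 2.51 for MPPED2, 0.91 for SNAI2, 0.81 for KRT8, -0.39 for KRT18, -0.61 for ZNF704, -0.66 for CCNE2, -0.67 for CENPE, -0.74 for HHEX, -1.08 for EHF, -1.77 for FAM160A1, -1.87 for SPTBN5, -2.68 for TXK and -2.73 for ANKRD1. Pseudogenes and non-coding or uncertain loci had 2.01 for LOC642423, 2 for UQCRBP1, -1.06 for LINC00707, -1.85 for RPLP0P2 and -3.16 for ZNF321P. FAP and SERPIND1 in SK-MEL-147 and CA9 in A375MA2 had too few counts to be tested within that line, and TXK and AKR1C2 in SK-MEL-147 and OASL and IFI27 in A375MA2 lie below 1 CPM. The size of their differences is therefore uncertain. Without the trend 59 of the 62 kept the call and the direction, and DHCR7 (0.25, adjusted p = 0.0519), PRRC2C (-0.34, 0.309) and ZNF704 (-0.36, 0.0546) lost it.

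The effect also differed between lines for 10 gene lists. The medians of the difference were 0.12 for p53 targets, -0.2 for G1/S genes, 0.22 for interferon-stimulated genes, -0.26 for heat shock genes and 0.19 for hypoxia and glycolysis genes, which all held with an estimated correlation. They were 0.24 for antigen presentation, 0.26 for NF-kB genes, 0.14 for matrix and adhesion genes, 0.06 for lysosome and autophagy genes and 0.16 for ribosomal proteins, whose adjusted p with an estimated correlation were 0.105, 0.133, 0.581, 0.257 and 0.758.

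In SK-MEL-147, 2295 genes were called with both shRNAs, and control libraries 1 and 3 differ from control library 2 and from the knockdown libraries in their length trend. When this trend was removed, 1216 genes (53%) kept the call and the direction, so the part of it that the splines capture does not account for those calls. A part of the trend that the removal left behind stays open for them. Their median log2 change along the called direction was 0.46 before and 0.35 after. As these genes were picked for keeping the call, that value is no separate evidence. For the other 1079 genes (47%) the median went from 0.37 (median SE 0.09) to 0.15 (0.06), but because they were picked for losing the call, the trend cannot be told apart from other sources for that part. That control libraries 1 and 3 stand apart for another reason cannot be told apart from knockdown, since sh2 against control 2 gave 20.3% of the change of sh1 against controls 1 and 3 (0.08 and 0.4 over 6664 genes, 66% in the same direction), between the bounds set for either outcome, and control 2 against controls 1 and 3, without knockdown, gave 0.23. An effect of G3BP1 loss stays open as the biological explanation of the genes that kept their call.

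Control library 3 of A375MA2 stands apart from the other libraries of its line on principal component 1. A knockdown library with a wrong label is excluded, since it holds 438 CPM of G3BP1, and so is RNA of the other line, since 13 genes abundant there and absent from the other A375MA2 libraries imply a share of 0.0202% (0.0285% in the other libraries). Its deviation from the other controls followed transcript length and GC content for 17.6% of the variance across 14528 genes and for 45.4% across the 9409 genes with a mean of at least 10 CPM. These shares were 8.1% and 33.3% for control library 1 and 21.8% and 52.2% for control library 2, so such a trend is not particular to library 3. The length and GC trend therefore cannot be told apart from other sources. The bound set for excluding it was not applied to 17.6% because counting noise of low genes enters that share. No biological explanation was tested, as the label gives none.

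In A375MA2 sh1 left more G3BP1 than sh2 and called more genes (1645 against 412). Of the 207 genes called with both shRNAs, 43% changed more with sh2, which argues against depth of knockdown alone setting their changes as a set. Effects particular to sh1 could lower that share, so a part that grows with depth stays open. In SK-MEL-147, where 52% of 2295 changed more with sh2, depth cannot be told apart from other sources. ESM1 did fall further with sh2 in A375MA2 (-2.32 against -1.17), and the 207 became 21 to 1470 with 1 library left out. Of 277 genes called between sh2 and sh1 in both lines, where 169 would be shared by chance, 202 (72.9%) went the same way. The exact binomial p was 1.26e-14, genes not being independent, and 68.5% of 983 did so with the trend removed. Effects that belong to each shRNA may give such a share. Over all 14042 genes tested in both lines the sh2 minus sh1 differences were weakly correlated (Pearson r 0.107, Spearman rho 0.179). Because sh2 lowered G3BP1 further in both lines, depth stays open for these 277 genes.

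Regrouping the libraries tested whether chance could give such counts. For each pairwise comparison there are 10 splits of 6 libraries, too few for a share under 0.05. The real counts were 1645, 412 and 883 in A375MA2 (sh1, sh2, sh2 against sh1) and 4823, 4740 and 3247 in SK-MEL-147, where 1 of 10 splits, the real one, gave as many genes, and the highest of the others gave 1, 0, 0, 0, 1 and 0. For genes called with both shRNAs in A375MA2, 2 of 100 regroupings of the 9 libraries gave as many as the real 207, so random labels seldom did. The highest other, 223, took the 3 sh1 libraries as the reference. By this count control against knockdown was therefore no more distinct than sh1 against the rest. Regroupings that mix true groups widen the spread within a group, so their low counts do not show knockdown to be the cause of the real ones. In SK-MEL-147 only the real grouping gave 2295 (1 of 100, highest other 1390, with the 3 sh1 libraries as the reference). For genes called in all 4 comparisons it was 1 of 100 (real 21, highest other 0). As regrouping also removes the calls within each line, this does not test the overlap of the lines. That overlap did not exceed chance in the main test (Fisher's exact p = 0.471 and 0.0601). With the trend removed it did, at 40 higher against 24.7 and 84 lower against 39.5 (Fisher's exact p = 0.00298 and 3.31e-11). Genes are not independent, as these tests take them to be, so the p values do not settle whether the lines share a response. Over all genes, Pearson's r of the mean effects in both lines instead went from 0.18 to 0.117. For the line difference only the real grouping, 1 of 60, gave as many genes (real 1421, highest other 73, with the 3 SK-MEL-147 sh2 libraries as the reference in that line).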

How the results depend on the processing

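The removal of each library's length and GC trend, SK-MEL-147 control library 2 as the only control of that line, and the trend removal without A375MA2 control library 3 were chosen after seeing the data. The G3BP1 and ESM1 calls kept their direction and passed the threshold in all 20 alternatives run for each call. The cut at an absolute log2 fold change of 1 was not run for single genes. G3BP1 with sh1 in SK-MEL-147 would not reach it. G3BP1 lay between -1.27 and -1.08 (sh1) and -2.18 and -2.05 (sh2) in A375MA2. In SK-MEL-147 it lay between -0.7 and -0.27 (sh1) and -1.34 and -0.9 (sh2). ESM1 lay between -1.23 and -1.04, -2.39 and -2.23, -1.27 and -1.02, and -1.63 and -1.45 in the same order. Counts of genes, by contrast, depend on the setting and on single libraries. For single named genes, settings fixed beforehand left 4856 values on the same side of the threshold. Of the others, 211 no longer passed it, 119 newly did and 0 changed sign with a call in either setting. Sign changes between values that neither setting called are counted among the first. Only the 6 libraries compared accounted for 82 of the 211, all 18 in 1 fit for 53, the replicate block for 30, library size for 27, no filter for 12, limma voom for 5, and the CPM filter and DESeq2 size factors for 1 each. Leaving out 1 library gave 4705, 516, 116 and 0, and the added settings 910, 138, 119 and 9.

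Left out in turn, single libraries gave these lowest and highest counts. In A375MA2 they were 507 and 3668 for sh1, 34 and 2527 for sh2, 253 and 2469 for sh2 against sh1, and 21 and 1470 for both shRNAs. In SK-MEL-147 they were 2669 and 6678, 2778 and 6732, 2029 and 4770, and 1023 and 4432. The 4 comparisons together gave 5 and 358 and the line difference 770 and 2926. Each high of a line came without its control library 2, except for sh2 against sh1 in A375MA2 and the line difference, which came without A375MA2 control library 3. Correlations across genes ranged from 0.474 to 0.7 (A375MA2), 0.459 to 0.688 (SK-MEL-147) and -0.002 to 0.291 (between lines), and lists called from 10 to 12 and 7 to 10 in A375MA2 and 11 to 12 and 10 to 14 in SK-MEL-147 (sh1, sh2). For G3BP1 the ranges were -1.25 to -1.18, -2.16 to -2.09, -0.45 to -0.27 and -1.09 to -0.9, and for ESM1 -1.23 to -1.08, -2.39 to -2.24, -1.27 to -1.05 and -1.63 to -1.49.

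An absolute log2 fold change of at least 1, which removes genes by construction, left 262, 58 and 158 genes in A375MA2 (sh1, sh2, sh2 against sh1) and 227, 359 and 189 in SK-MEL-147. It left 29 and 80 with both shRNAs, 1 in all 4 comparisons and 265 for the line difference. The cause was not tested for the changes that follow, except that fewer libraries or residual degrees of freedom enter where libraries were left out. DESeq2 called 2762 (1345 higher, 1417 lower), 1489 (723, 766) and 1701 in A375MA2, 733 with both shRNAs, 114 in all 4 and 2384 for the line difference. All 18 libraries in 1 fit gave 1112 with sh2 in A375MA2, 557 and 1270 with both shRNAs and 72 in all 4. Only the 6 libraries compared gave 485, 15 and 3163 in A375MA2. The replicate block gave 163 with sh2 and 571 for sh2 against sh1 in A375MA2, 89 with both shRNAs and 8 in all 4. Replicate numbers did not pair the libraries in SK-MEL-147, and whether they do in A375MA2 stays open. After removing group means, libraries with the same number correlated above 0.1 in 2 of 9 pairs in A375MA2 (-0.228 to 0.33) and in 0 of 9 in SK-MEL-147 (-0.028 to 0.048). In A375MA2, 6 of 9 libraries correlated best with a library of their own number, against 2 of 9 in SK-MEL-147. The median in A375MA2 was 0.012 for same-number pairs and -0.0085 for other pairs. An estimated correlation left 2, 1, 1 and 1 lists, and fry called 20 with sh1 in SK-MEL-147. Among genes with a mean of at least 10 CPM the lines correlated at 0.427, with the trend not removed.

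Removing the trend gave 3787, 1951 and 2451 in A375MA2, 1079 with both shRNAs there, 124 in all 4 and 2822 for the line difference. Values that changed sign in SK-MEL-147, with a call in either fit, were -0.04 (ANTXR2), 0.04 (ADRM1), -0.01 (DDX3X), 0.01 (BAX) and -0.3 (PRRC2C) with sh1. With sh2 they were 0.03 (ZYX), -0.11 (PRRC2C) and -0.2 (CENPE). Of these only PRRC2C with sh1 (adjusted p = 0.00451) and CENPE with sh2 (0.0188) passed the threshold. SK-MEL-147 control library 2 as the only control, whose spread is assumed to be that of the other groups, gave 1357, 1422, 332 with both shRNAs, 6 in all 4 and 238 for the line difference, and 0.02 for ADRM1 with sh1. Trend removal without A375MA2 control library 3 gave 4684, 2855 and 4495 in A375MA2, 1607 with both shRNAs, 207 in all 4 and 3514 for the line difference.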

Other observations

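The removal of the length and GC trend was chosen after seeing the data, and the levels compared between lines were not tested. The lines differ in their control state. MITF, the regulator of the melanocyte lineage, was at 64.8 ± 4.99 CPM (SD, n = 3, scaled over all 18 libraries) in A375MA2 controls and 9.17 ± 2.38 in SK-MEL-147 controls. The receptor kinase AXL, high in undifferentiated melanoma, was at 184 ± 9.77 and 1840 ± 64.8. NGFR, a marker of neural-crest-like cells, was at 5.15 ± 1.75 and 96 ± 3.79, SOX9 at 0.149 ± 0.2 and 29 ± 1.76, and the mesenchymal filament gene VIM at 4190 ± 324 and 8260 ± 548. SOX10, a neural crest factor, was abundant in both (601 ± 103 and 448 ± 15.9). The pigment genes PMEL (0.899 ± 0.0863 and 0.465 ± 0.0839) and MLANA (0.0815 ± 0.0318 and 0.0427 ± 0.0471) were near 0 in both lines, and TYR had 0 counts in all 6 control libraries. G3BP1 itself stood at 400 ± 19.9 and 188 ± 26.5.

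A further 5 lists were not called in any comparison by camera with all libraries as measured. Secreted angiogenic factors had 3 members higher and 5 lower of 19 with sh1 in A375MA2, 3 and 2 with sh2, and 5 and 6, then 3 and 7 of 22 in SK-MEL-147 (adjusted p = 0.425, 0.731, 0.777 and 0.256). Adjusted over the list alone the counts were 4 and 6, 4 and 3, 6 and 7, and 3 and 7. ANGPTL4, a regulator of lipid uptake and vessels, fell with sh1 (-1.05 ± 0.14) and sh2 (-0.70 ± 0.14, a call lost with 7 of 9 libraries left out in turn) in A375MA2 and in SK-MEL-147 rose with sh1 (0.60 ± 0.10) and fell with sh2 (-0.86 ± 0.10). THBS1, an anti-angiogenic matrix protein, fell with sh1 in A375MA2 (-1.07 ± 0.12) and rose with sh1 (0.47 ± 0.07) and fell with sh2 (-0.36 ± 0.07) in SK-MEL-147, at 0.21 and -0.64 with the trend removed. Pro-apoptotic genes had 1 and 2, then 1 and 0 of 28 in A375MA2 and 1 and 9, then 3 and 7 in SK-MEL-147 (0.448, 0.776, 0.0707 and 0.522). These were 1 and 2, 1 and 0, 1 and 9, and 4 and 8 adjusted over the list alone. Among them the BH3-only gene BMF rose with both shRNAs in A375MA2 (0.90 ± 0.10 and 0.67 ± 0.10, the sh2 call lost with 2 libraries left out) and in SK-MEL-147 fell with sh1 (-0.45 ± 0.08) and rose with sh2 (0.39 ± 0.08). Anti-apoptotic genes had 1 and 3, then 0 and 1 of 14 in A375MA2 and 3 and 5, then 5 and 1 in SK-MEL-147 (0.121, 0.711, 0.269 and 0.303). These were 1 and 4, 2 and 2, 3 and 6, and 6 and 3 adjusted over the list alone, and BIRC6 rose with both shRNAs in SK-MEL-147 (0.70 ± 0.16 and 0.76 ± 0.16, and 0.37 and 0.42 with the trend removed). Lysosome and autophagy genes had 4 and 2, then 2 and 2 of 28 in A375MA2 and 2 and 9, then 3 and 4 in SK-MEL-147 (0.342, 0.507, 0.117 and 0.507). These were 6 and 3, 5 and 7, 2 and 10, and 3 and 2 adjusted over the list alone. The autophagy gene WIPI1 rose with sh1 in A375MA2 (0.68 ± 0.07). G2/M genes had 0 and 2 of 30 with sh1 in A375MA2, 0 with sh2 by edgeR (5 lower at an unadjusted p below 0.05, 2 lower by DESeq2, 0 by limma voom). They had 9 and 3 with sh1 and 4 and 6 with sh2 in SK-MEL-147 (0.229, 0.404, 0.207 and 0.626). These were 0 and 1, 0 and 1, 9 and 4, and 5 and 7 adjusted over the list alone. Here the mitotic kinase AURKB fell with sh2 in SK-MEL-147 (-0.40 ± 0.08, and -0.17 with the trend removed) and the kinesin CENPE rose with sh1 (0.54 ± 0.08, and 0.24). With sh2 CENPE was not called (0.10 ± 0.08) but was called lower once the trend was removed (-0.2, adjusted p = 0.0188).

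Median, mean and test of a list differed in sign in some comparisons in which camera did not call it. This was so for pro-apoptotic, anti-apoptotic, p53, oxidative stress and SRF genes with sh2 in A375MA2, for p53, ERK output, melanocytic, invasive melanoma and endothelial genes with sh1 in A375MA2. In SK-MEL-147 it was so for stress response, invasive melanoma, matrix, angiogenic and leukocyte genes with sh1, and for study, pro-apoptotic, heat shock, YAP and TAZ, and leukocyte genes with sh2. Removing the trend added 7 list calls by camera. G2/M genes with sh1 in SK-MEL-147 were called higher (adjusted p = 0.0477, 10 members higher and 1 lower). Called lower were ERK output genes (0.0428) and epithelial markers (0.04) with sh2 in A375MA2, ERK output genes with sh1 in SK-MEL-147 (0.043), SRF and actin genes with sh2 there (0.00626), and the study genes with both shRNAs of that line.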
